A study of Mus musculus with 10 samples.

How the data were processed

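RNA from sorted EpCAM-positive, DAPI-excluding stomach corpus cells was measured in 10 libraries of 4 groups. Per the labels' protocols, gastric units were released with EDTA and DTT, digested to single cells, strained, stained and sorted on a FACSAria II, and RNA was extracted with a kit for small cell numbers and sent to BGI, which amplified it by PCR, prepared the libraries and sequenced them. Per the submitters' processing notes, STAR 2.7.1a, featureCounts, Subread 2.0.0 and edgeR were used with the mouse build GRCm38 (mm10). Strandedness, read filters and the scaling between libraries are not given in the sources used here, so reads of overlapping, antisense and near-identical genes cannot be told apart.

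The authors deposited 1 table of log2 CPM values for 55276 genes in the 10 libraries. From the values, the deposited log2 numbers carry no pseudocount, and every gene below 1 CPM is listed at 0. A gene listed at 0 is therefore below 1 CPM and not necessarily without reads, and a difference against a listed 0 depends on that floor, so such genes are given by library values without a fold. In each library the CPM of every gene above the floor was a whole multiple of 1 step, within 0.05 read for 100% of the values, which gave the library total. The listed CPM of a library summed to between 1036666 and 1053761, above the base of the unit, so the authors' library total is smaller than the reads listed, for a reason not given in the sources used here. These totals, as used for CPM, ran from 47432129 to 264816271 reads. Intervals of read shares are Wilson intervals at 95%, and they cover counting error only, since PCR reads without molecular identifiers are not independent molecules. In 26 places a gene symbol had been turned into a date, with 24 distinct dates. Of these, 20 entered the test under a date and are not named. Symbols were matched to a GENCODE annotation of GRCm38, which held 53362 of the 55276, for the coordinates given. Cblif stands for the older symbol Gif.

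Groups were taken from the titles and characteristics in the labels. Each library is a pool of 3 or 4 mice, so p-values measure the spread between libraries of pooled mice. If libraries with the same number come from the same mice, there are 5 pools, while the main fit takes all 10 libraries as independent. Titles also carry a 4-digit code, 1909, 1910 and 2003 for WT replicates 1, 2 and 3 and 1910 and 2020 for R122C replicates 1 and 2. The meaning of the code is not given in the sources used here. Only 1910 occurs in both genotypes, so values within it are given in case the code marks a batch. With the code as a term, the genotype difference averaged over the fractions also rests on 1910 alone, with 1 library per genotype and fraction. The labels do not say that IQ3pos and IQ3neg libraries with the same number come from the same mice, and differences between them are given as differences within a title code.

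Differences were tested with limma 3.58.1 in R 4.3.3, a linear model with 4 group means on the deposited log2 values of all 10 libraries, moderated with an intensity trend (6 residual and 6.01 prior degrees of freedom). Sharing 1 estimate of spread over the groups let the R122C groups of 2 be tested. Genes above the listed 0 in at least 2 libraries were kept, which left 17155. Tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. The comparisons were IQ3pos against IQ3neg in WT and in R122C, R122C against WT in IQ3pos and in IQ3neg, and the interaction of fraction and genotype. Since 3 libraries against 2 or 3 give too few permutations for a test over all genes, no permutation p is given.

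The groups, comparisons, tests, 33 gene lists, naming rule and most alternatives were fixed before the data were examined. The lists covered cell division (mitosis, DNA replication, MYC targets and ribosome biogenesis), stem and progenitor candidates, corpus lineages (surface pit, mucous neck, chief, parietal, enteroendocrine and tuft cells), metaplasia and intestinal genes, WNT, TGF-beta and p53 targets, the RUNX family, immediate early genes, interferon response, MHC class II, the unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, the nuclear respiratory chain, mitochondrially encoded transcripts, cytosolic ribosomal proteins, other cells a sort could hold (immune, fibroblast and muscle, endothelial, erythroid, squamous forestomach, pancreatic acinar and antral) and sex-linked genes. A list needed 3 tested members, which left out the erythroid list. Lists share members: 5 of the 14 stem candidates, 5 of the 15 metaplasia genes, 4 of the 8 mucous neck genes, 5 of the 12 WNT targets and 3 of the 5 antral genes are also in another list, while the mitosis, DNA replication, pit, tuft, pancreatic and mitochondrial lists share none. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance one way. With an estimated correlation only the enteroendocrine and pancreatic acinar lists passed, in both fraction comparisons, and none passed between genotypes or in the interaction. List values are medians of log2 differences.

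Genes named were, per comparison, the 5 largest rises and 5 largest falls among called genes with a mean log2 CPM of at least 3 in the higher group and no overlap between the groups, up to 4 called members of each list by smallest p or, where none was called, its 2 most highly expressed members, and 20 fixed genes. Unnamed transcripts and immunoglobulin and T cell receptor segments were left out of the largest changes. Other genes named are said to be chosen after their values were seen.

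Alternatives were no filter, a filter at 5 CPM, quantile normalization, median centring, log2(CPM + 1), moderation without trend or robust, library weights, only the groups compared, a fixed or random block for libraries sharing a number, the title code as a term, a log2 threshold of 1, voom on the recovered reads, and leaving out each library. After the data were seen, fits without both libraries of WT replicate 1 were added, and the list tests were rerun with median centring, the block, the title code and each library left out. The calculations were tested on simulated data with 200 of 17155 genes changed, all drawn from genes with a mean log2 CPM of at least 4. Values were drawn independently from normal distributions, without shared pools or the drops to a listed 0 seen in the data. The rates below therefore do not hold for all genes tested. Between the WT fractions 0%, 23.9% and 80.3% of changes of 1, 2 and 4 on the log2 scale were recovered, with 5 false calls among 74, between the R122C fractions 0%, 4.48% and 72.7%, between genotypes in IQ3pos 2.99%, 17.9% and 80.3%, and in IQ3neg 0%, 19.4% and 80.3%.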

Results

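RNA was sequenced from sorted epithelial cells of the stomach corpus, the acid-secreting body of the stomach, of C57BL/6 mice aged 6 to 8 weeks. The mice were wild type for Runx3 (WT) or carried R122C, an arginine-to-cysteine change in RUNX3, a transcription factor of the Runt family. All carried a reporter that makes the red fluorescent protein tdTomato together with Iqgap3, a scaffold protein. EpCAM-positive living cells were sorted into a tdTomato-positive, Iqgap3-high fraction (IQ3pos) and a tdTomato-negative, Iqgap3-low or negative fraction (IQ3neg). The 4 groups were WT IQ3pos (n = 3), WT IQ3neg (n = 3), R122C IQ3pos (n = 2) and R122C IQ3neg (n = 2). Each library came from a pool of 3 mice, except the pair of WT replicate 2 libraries, which came from 4. The comparisons bear on which cell types and programmes separate the fractions, and on whether the R122C change alters how stem cells of the gland isthmus multiply and mature, the question the series title raises.

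Library totals as used for CPM, read back from the steps between values, ran from 47.4 M to 265 M reads. So 1 CPM, the lowest level the table lists, stood for 47.4 to 264.8 reads. The listed genes held more reads than these totals, from 49.8 M to 278 M. Between 11879 and 14811 genes per library stood at 1 CPM or more. The WT replicate 1 pair was the shallowest, at 49.8 M listed reads in IQ3pos and 61.5 M in IQ3neg. WT IQ3neg replicate 1 also stood apart in the share of listed reads on Clps, the gene of pancreatic colipase, at 32.1% (Wilson 95% interval 32.14 to 32.16), against 9.33% and 9.23% in the other WT IQ3neg libraries and 11.5% and 12.9% in R122C IQ3neg. Its 10 most abundant genes took 57.7% of the listed reads, against 25.02% to 33.4% in the other IQ3neg libraries. No Wilson interval of such a share was wider than 0.0247 percentage points in any library.

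Runx3, on GRCm38 chromosome 4 from 135120652 to 135177990, was listed at 0, meaning below 1 CPM, in 8 of the 10 libraries. WT IQ3neg replicates 2 and 3 held log2 CPM values of 1.27 and 1.04 (adjusted p = 0.265 for IQ3pos against IQ3neg in WT). A point change need not alter the transcript level, so Runx3 does not check the genotype labels here. Iqgap3 (chromosome 3, 88081971 to 88121048) was listed at 0 in 7 of the 10 libraries. It reached log2 CPM 3.16 in WT IQ3pos replicate 2, 2.28 in R122C IQ3pos replicate 1 and 0.22 in R122C IQ3neg replicate 1 (adjusted p = 0.509 in WT and 0.845 in R122C between the fractions). The sort was made on the reporter, whose own transcript was not analysed here.

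In WT mice, genes of cell division were higher in IQ3pos than in IQ3neg. Top2a (chromosome 11, 98992943 to 99024189), a topoisomerase that separates replicated DNA, stood at log2 CPM 9.10 ± 0.588 (SD, n = 3) in IQ3pos and 5.81 ± 0.889 in IQ3neg, a 9.74-fold rise (log2 difference 3.29 ± 0.464 SE, adjusted p = 0.00464). Kif20b, a kinesin of cytokinesis, rose by 4.41 ± 0.542 (adjusted p = 0.0021), and the proliferation marker Mki67 (chromosome 7, 135689784 to 135716361) rose 5.47-fold, from 5.51 ± 0.562 to 7.96 ± 0.603 (adjusted p = 0.0236). Nusap1, a spindle protein, stood at 6.52, 8.04 and 7.58 in the IQ3pos libraries against a listed 0, 3.28 and 3.74 in IQ3neg (adjusted p = 0.0152). Of the 25 tested genes of the mitosis list, 12 rose, none fell and 13 did not pass, with 23 rising when adjusted over the list alone. Their log2 differences were all above 0, from 0.23 to 5.04 with a median of 3.38 (camera adjusted p = 8.29e-19, and adjusted p = 0.42 with an estimated correlation). Between IQ3pos and IQ3neg libraries with the same title code the median was 4.45, 2.99 and 2.52, and Top2a differed by 3.63, 2.99 and 3.23. The first of each set of values includes WT IQ3neg replicate 1, whose mitosis median of 1.64 lay under the 4.73 and 4.37 of the other WT IQ3neg libraries. In that library 9 of the 25 mitosis genes were listed at 0, against none in the other WT IQ3neg libraries. The differences of those genes therefore depend on the floor.

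Some genes of DNA synthesis rose as well. Rrm2, a subunit of ribonucleotide reductase, rose by 2.69 ± 0.461 (adjusted p = 0.0145), and 4 of the 28 DNA replication genes rose over all genes tested, with 17 when adjusted over the list alone. The list's median was 2.01 (camera adjusted p = 3e-12, and adjusted p = 0.42 with an estimated correlation). In WT IQ3neg replicates 1, 2 and 3, 7, 3 and 1 of its genes were listed at 0. Stmn1, a tubulin-binding protein of dividing cells, was 2.48 ± 0.621 higher and did not pass (adjusted p = 0.0646, and 0.0314 with a block for libraries sharing a number). None of the 22 MYC target and ribosome biogenesis genes passed over all genes (9 higher when adjusted over the list alone), while the list's median was 1.30 (camera adjusted p = 3.65e-06, and adjusted p = 0.533 with an estimated correlation) and 0.78 without WT IQ3neg replicate 1. Calls for Top2a and Kif20b held without any single WT library. Without IQ3pos replicate 2, IQ3neg replicate 2 and IQ3pos replicate 3 in turn, the adjusted p was 0.0882, 0.0535 and 0.0835 for Nusap1, 0.0774, 0.0596 and 0.0785 for Rrm2, and 0.1, 0.0648 and 0.107 for Mki67, which also stood at 0.0528 without IQ3neg replicate 1.

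Genes of 3 secreted proteins of surface pit cells, the mucous cells that line the stomach, rose in WT IQ3pos. Gkn1 (chromosome 6, 87345650 to 87350942), a gastrokine, stood at log2 CPM 12.41 ± 0.274 in IQ3pos and 10.11 ± 0.992 in IQ3neg (log2 difference 2.29 ± 0.499, adjusted p = 0.0389). Its neighbour Gkn2 rose by 2.41 ± 0.538 (adjusted p = 0.043) and the trefoil factor Tff1 by 2.38 ± 0.521 (adjusted p = 0.0402), while the mucin Muc5ac was 2.43 ± 0.667 higher without passing (adjusted p = 0.0859). Of the 14 pit cell genes 3 rose and none fell, against 8 higher and 1 lower when adjusted over the list alone. Psca, a gene of the list singled out after its values were seen, went the other way without passing. It stood at 11.21, 11.14 and 11.12 in IQ3pos against 12.75, 13.28 and 12.56 in IQ3neg. The list's median of 1.76 had a camera adjusted p of 0.00057, and adjusted p = 0.533 with an estimated correlation, and within the title codes it was 2.94, 1.55 and 1.20. Without WT IQ3neg replicate 1 it was 1.14. The call of Gkn1 held in 1 of the 6 fits that left out a library: adjusted p was 0.11, 0.118 and 0.172 without IQ3pos replicates 1, 2 and 3, and 0.0553 and 0.145 without IQ3neg replicates 1 and 2. In the same 5 fits it was 0.0974, 0.125, 0.18, 0.056 and 0.135 for Gkn2, and 0.111, 0.135, 0.157, 0.0682 and 0.13 for Tff1. In the mucous neck list none of the 8 genes passed (median 0.53, camera adjusted p = 0.154). Tff2 was 2.36 ± 0.597 higher (adjusted p = 0.0668) and Muc6 differed by -0.40 ± 0.591 (adjusted p = 0.75). The calls of Muc5ac and Tff2 depended on the fit: in limma with a block for libraries sharing a number, adjusted p was 0.0269 and 0.0371.

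Among genes of chief and parietal cells, 1 passed. Cblif, which encodes gastric intrinsic factor and marks mouse chief cells, fell 12.3-fold in WT IQ3pos (9.93 ± 0.66 against 13.55 ± 0.493, adjusted p = 0.00273), and its call held without any single WT library. Pgc, the pepsinogen C gene, differed by -1.82 ± 0.55 (adjusted p = 0.115). Bhlha15, a transcription factor of secretory cells, was listed at 0 in every WT IQ3pos library and stood at 2.30 ± 0.673 in IQ3neg (adjusted p = 0.136). The chief cell list had a median of -1.56, with 1 of 10 genes lower and 4 when adjusted over the list alone (camera adjusted p = 0.0055, adjusted p = 0.464 with an estimated correlation, and 0.0753 without WT IQ3pos replicate 3). None of the 19 parietal cell genes passed (4 higher and 1 lower when adjusted over the list alone). Atp4a and Atp4b, the subunits of the acid pump, were 1.11 ± 0.838 and 1.94 ± 0.607 higher (adjusted p = 0.506 and 0.128). The parietal median of 1.14 (camera adjusted p = 0.0059, adjusted p = 0.533 with an estimated correlation) was 1.22 with adjusted p = 0.1 without WT IQ3pos replicate 1, and 0.76 with adjusted p = 0.151 without that pair of replicate 1 libraries. Without WT IQ3neg replicate 1 alone it was 0.74.

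Hormone genes of enteroendocrine cells were far lower in WT IQ3pos. Sst, which encodes somatostatin (chromosome 16, 23889573 to 23890958), fell 62.8-fold, from log2 CPM 12.51 ± 0.507 in IQ3neg to 6.53 ± 0.503 in IQ3pos (adjusted p = 2.94e-05). Chga, the granule protein chromogranin A, fell 54.4-fold (log2 difference -5.77 ± 0.387, adjusted p = 3.54e-05), and the ghrelin gene Ghrl fell 45.8-fold (-5.52 ± 0.486, adjusted p = 0.000152). Gcg, the proglucagon gene, was listed at 0 in the 3 IQ3pos libraries and stood at 7.85 ± 0.42 in IQ3neg (adjusted p = 0.000103). Serpina7, which encodes thyroxine-binding globulin, was likewise listed at 0 against 7.92 ± 0.231 (adjusted p = 0.000293). Snap25, a protein of vesicle fusion, stood at 0.51 in 1 IQ3pos library and was listed at 0 in the other two, against 7.26 to 7.89 in IQ3neg (adjusted p = 5.96e-05). Of the 15 enteroendocrine genes 9 fell and none rose, with 10 falling when adjusted over the list alone. The list's median of -3.18 passed with the preset correlation (camera adjusted p = 8.29e-19) and with an estimated correlation (adjusted p = 0.0134). Within the title codes Sst differed by -6.20, -6.43 and -5.28. The calls of these genes held without any single WT library.

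A tuft cell gene and several genes of digestive enzymes fell as well. Trpm5, the cation channel of tuft cells, stood at 3.39, a listed 0 and 0.29 in WT IQ3pos and at 5.03, 6.88 and 6.15 in IQ3neg (adjusted p = 0.0389). It was the 1 of 15 tuft cell genes that fell, with 11 when adjusted over the list alone, and the list's median was -2.27 (camera adjusted p = 4.58e-10, and adjusted p = 0.42 with an estimated correlation). Within the title codes that median was 0.03, -3.32 and -3.06, and without the pair of WT replicate 1 libraries it was -3.52. Try4, a trypsin gene, fell by 4.58 ± 0.538 (adjusted p = 0.00156), and Cel, a bile-salt-activated lipase, stood at 3.88, 0 and 2.49 in IQ3pos against 9.14, 10.05 and 9.26 in IQ3neg (adjusted p = 0.0101). The pancreatic acinar list, fixed as markers of another organ, had 5 of 10 genes lower and 6 when adjusted over the list alone. Its median was -2.29 (camera adjusted p = 4.7e-09, and adjusted p = 0.0134 with an estimated correlation). Clps, a member of that list singled out after its values were seen, is among the 5 genes counted. It fell by 3.87 ± 0.841 (adjusted p = 0.0389). Its call held without IQ3neg replicate 3, while adjusted p was 0.0646, 0.191 and 0.261 without IQ3pos replicates 1, 2 and 3 and 0.066 and 0.117 without IQ3neg replicates 1 and 2. Trpm5 passed without IQ3pos replicate 1 and stood at adjusted p = 0.0615, 0.155 and 0.0838 without IQ3neg replicates 1, 2 and 3, and 0.13 and 0.143 without IQ3pos replicates 2 and 3. In limma with a block for libraries sharing a number, its adjusted p was 0.0667. Cel stood at 0.0604, 0.0653 and 0.0531 without IQ3pos replicate 2, IQ3neg replicate 2 and IQ3pos replicate 3.

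Other lists moved less or in mixed directions. Among 14 stem and progenitor candidates Hmgb2, a chromatin protein, rose by 2.86 ± 0.516 (adjusted p = 0.0178), Ezh2, a histone methyltransferase, rose by 3.09 ± 0.604 (adjusted p = 0.0256), and Msi1, an RNA-binding protein, was lower, at 2.62 or less in each IQ3pos library against 5.62 or more in IQ3neg (adjusted p = 0.011). Lrig1, a receptor regulator used as a stem cell marker, differed by -0.15 ± 0.817 (adjusted p = 0.947). That list's median was near 0 with a mean of -0.32 (camera adjusted p = 0.908). In each of the metaplasia, intestinal and p53 target lists 1 gene was lower: Ceacam10 (-5.80 ± 0.867, adjusted p = 0.00707) of 15, Tff3 (adjusted p = 0.014) of 12 and Trp53inp1 (adjusted p = 0.0152) of 14. Their list tests gave 0.918, 0.379 and 0.32. Without IQ3pos replicate 2, IQ3neg replicate 2 and IQ3pos replicate 3 in turn, adjusted p was 0.0907, 0.0744 and 0.0947 for Hmgb2, 0.0914, 0.0877 and 0.065 for Ezh2 (0.0843 without IQ3pos replicate 1), 0.053, 0.0548 and 0.0524 for Ceacam10, and 0.0539, 0.0774 and 0.0587 for Trp53inp1. Without IQ3neg replicate 2 it was 0.072 for Msi1 and 0.0707 for Tff3, which stood at 0.0534 without IQ3pos replicate 3.

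No single gene passed in the lists of nuclear respiratory chain genes (99 tested, median 0.88, camera adjusted p = 1.32e-14), cytosolic ribosomal proteins (86, 1.14, 3.15e-19), cholesterol synthesis (15, 1.08, 0.0064) and mitochondrially encoded transcripts (13, 0.63, 0.0361), all higher in IQ3pos as sets. With an estimated correlation their adjusted p was 0.533, 0.533, 0.629 and 0.693. Adjusted over the list alone, 56 ribosomal genes were higher and none in the other lists. Without the pair of WT replicate 1 libraries the respiratory median was 0.49. The cholesterol set stood at adjusted p = 0.109 without WT IQ3pos replicate 2, with a median of 0.46 without WT IQ3neg replicate 1. The mitochondrial set stood at 0.281 and 0.0753 without WT IQ3pos replicates 1 and 3 and at 0.441 and 0.146 without WT IQ3neg replicates 2 and 3, and its median was 1.10 without IQ3neg replicate 1 and 1.09 without IQ3pos replicate 2. Immune cell genes were lower as a set (17, median -0.80, camera adjusted p = 0.00603, and adjusted p = 0.533 with an estimated correlation). That call was lost without WT IQ3neg replicate 1 (median -0.18, adjusted p = 0.621) and without the pair of replicate 1 libraries (0.199), and the median was -1.23 without WT IQ3neg replicate 3.

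Sets without a call in WT were WNT targets (median -0.18, camera adjusted p = 0.379), TGF-beta targets (0.88, 0.181), the RUNX family (-0.87, 0.0763), immediate early genes (-0.46, 0.0734), interferon response (0.36, 0.524), MHC class II (-0.43, 0.379), unfolded protein response (-0.02, 0.289), and glycolysis and hypoxia (0.44, 0.467). The same held for markers of fibroblast and muscle (-0.52, 0.261), endothelial (-0.10, 0.717), squamous forestomach (0.12 with a mean of -0.01, 0.833) and antral (0.59, 0.662) cells and for sex-linked genes (-0.16, 0.49). Of the fixed single genes, Myc was 1.67 ± 0.848 higher (adjusted p = 0.313), Ccnd1 0.59 ± 0.679 higher (0.668) and the cell cycle inhibitor Cdkn1a differed by -1.48 ± 0.479 (0.138).

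Over all 17155 genes tested, limma called 348 between the WT fractions, 104 higher and 244 lower in IQ3pos. With each library centred on its median the split was 510 higher and 388 lower, and with a block for libraries sharing a number it was 189 higher and 175 lower. Without IQ3pos replicates 1, 2 and 3 the count was 219, 108 and 90, without IQ3neg replicate 2 it was 78, and without the pair of WT replicate 1 libraries 220, of which 139 were among the 348. With only the 2 WT groups in the fit it was 34, all lower in IQ3pos, so no rise passed there.

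**Figure D1:**
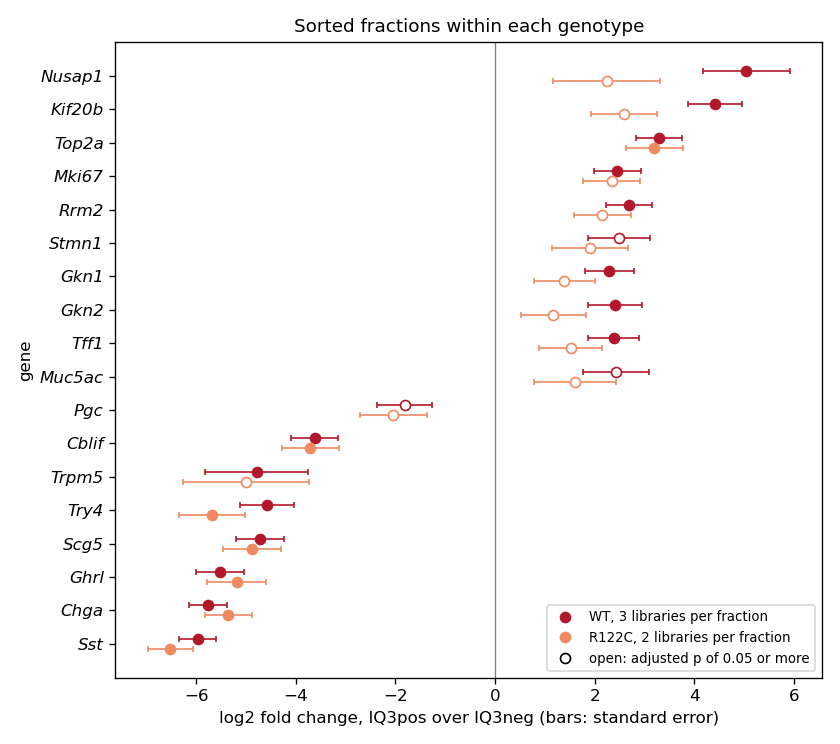
Log2 difference between IQ3pos and IQ3neg (x axis, log2 CPM units) for genes of cell division, pit cells, chief cells, tuft cells, a trypsin gene and enteroendocrine cells, in WT (n = 3 per fraction) and R122C (n = 2 per fraction), with bars for 1 SE and filled points for an adjusted p under 0.05. Top2a rose by 3.29 in WT and 3.19 in R122C, and Sst differed by -5.97 and -6.52. The points of Nusap1 in WT and of Trpm5 in both genotypes include a library listed at 0, so they depend on that floor.

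In R122C mice the fractions were separated by some of the same genes. Sst fell by 6.52 ± 0.455 in IQ3pos (5.40 ± 0.106 against 11.92 ± 0.173, SD, n = 2, adjusted p = 0.00011), Chga fell by 5.36 ± 0.474 (adjusted p = 0.000795) and Ghrl fell by 5.19 ± 0.595 (adjusted p = 0.00426). Top2a rose by 3.19 ± 0.568, from 6.09 ± 0.062 to 9.28 ± 0.343 (adjusted p = 0.0403). Cblif fell by 3.71 ± 0.576 (adjusted p = 0.0184) and Try4 fell by 5.68 ± 0.659 (adjusted p = 0.00426). Mki67 was 2.34 ± 0.573 higher without passing (adjusted p = 0.165), as were Gkn1 (1.39 ± 0.611, 0.585), Muc5ac (1.60 ± 0.817, 0.68) and Stmn1 (1.90 ± 0.76, 0.507). Of the 5 genes called higher, Depdc7, Ccdc63 and Rhobtb2 were listed at 0 in both R122C IQ3neg libraries. They stood at 3.93 ± 0.285, 3.22 ± 0.39 and 3.06 ± 0.75 in IQ3pos (adjusted p = 0.0281, 0.0184 and 0.0353). In limma with a block for libraries sharing a number these 3 genes did not pass (adjusted p = 0.101, 0.0879 and 0.122), nor did Cblif (0.0507). All 3 were listed at 0 in every WT IQ3pos library. In WT IQ3neg they were listed at 0 except Depdc7 at 1.17 in replicate 2 and Rhobtb2 at 0.34 in replicate 1. The interaction had adjusted p = 1 for each. R122C against WT in IQ3pos did not pass either (limma adjusted p = 0.0772, 0.0772 and 0.0816). There Depdc7 and Ccdc63 were called with quantile normalization, without trend and by voom, Ccdc63 with library weights and Rhobtb2 by voom. Other fits on all 10 libraries did not call them. Jchain, the joining chain of secreted immunoglobulins, was listed at 0 in both IQ3pos libraries against 8.21 ± 0.0904 in IQ3neg (adjusted p = 0.012).

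By list, 7 of 15 enteroendocrine genes fell in R122C IQ3pos, with 9 when adjusted over the list alone (median -3.45, camera adjusted p = 7.23e-24, and adjusted p = 0.00657 with an estimated correlation). Of the pancreatic acinar genes 1 of 10 fell, with 6 when adjusted over the list alone (-2.35, 8.2e-11, and adjusted p = 0.00657 with an estimated correlation). Only Top2a rose among 25 mitosis genes, with 9 when adjusted over the list alone, while all 25 differences were above 0 (2.24, 4.69e-15, and adjusted p = 0.43 with an estimated correlation). None of 28 DNA replication genes passed, with 3 higher when adjusted over the list alone (1.84, 7.52e-11, and adjusted p = 0.43 with an estimated correlation). Tuft cell genes had a median of -2.63 (0 of 15, with 8 lower when adjusted over the list alone, 4.69e-11, and adjusted p = 0.364 with an estimated correlation). The chief cell median was -1.71 (1 of 10, with 5 lower when adjusted over the list alone, 0.000167, and adjusted p = 0.364 with an estimated correlation). Sets of MYC targets (0.86, 0.000148), pit cells (1.25, 0.00844), respiratory chain (0.55, 1.75e-08) and ribosomal proteins (0.74, 1.47e-11) were higher with no single gene passing, and each had adjusted p = 0.804 with an estimated correlation. The pit cell call was lost without R122C IQ3pos replicate 1 (adjusted p = 0.0914). Without R122C IQ3neg replicate 1 the respiratory and ribosomal calls were lost (medians 0.21 and 0.33, adjusted p = 0.22 and 0.0625), without IQ3neg replicate 2 the medians were 0.87 and 1.15, and without IQ3pos replicate 2 the ribosomal median was 0.48.

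The remaining R122C sets had no call. They included parietal cells (median 0.10 with a mean of -0.28, adjusted p = 0.971), stem and progenitor candidates (-0.58, 0.427), mucous neck cells (0.49, 0.335), cholesterol synthesis (0.33, 0.0987), mitochondrially encoded transcripts (-0.35, 0.491), immune cells (-0.14, 0.0987) and immediate early genes (-0.47, 0.0987). Within the title codes the mitosis median was 2.91 and 1.47, Top2a differed by 3.39 and 2.99, and Sst by -6.72 and -6.32. Limma called 55 genes, 5 higher and 50 lower, against 18 higher and 69 lower with median centring, which shifted the median of all genes by 0.168. Without IQ3neg replicate 1, IQ3pos replicate 2 and IQ3neg replicate 2 the count was 17, 21 and 22. Of the genes named, Sst and Chga kept their calls without any single R122C library. Without IQ3pos replicate 1, IQ3neg replicate 1, IQ3pos replicate 2 and IQ3neg replicate 2 in turn, adjusted p was 0.22, 0.26, 0.218 and 0.189 for Top2a, 0.0878, 0.187, 0.284 and 0.097 for Cblif, 0.0229, 0.0942, 0.0843 and 0.063 for Ghrl, 0.0124, 0.0942, 0.047 and 0.0597 for Try4, 0.0835, 0.166, 0.118 and 0.129 for Jchain, 0.0397, 0.162, 0.0853 and 0.116 for Depdc7, 0.0169, 0.0942, 0.0426 and 0.0684 for Ccdc63, and 0.0494, 0.166, 0.0375 and 0.116 for Rhobtb2.

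The fraction calls of the genotypes overlapped. Their contrasts share no library, but both use 1 estimate of each gene's spread over all 10 libraries, so the lists are not independent. With only the 2 groups compared, 34 genes were called in WT and 0 in R122C, which leaves no overlap. Of the genes lower in IQ3pos, 45 were called in both (244 in WT and 50 in R122C, with 0.711 given by independent lists of these sizes), and of the genes higher, Top2a was the 1 called in both (104 and 5, with 0.0303 given by independent lists). Of the WT calls, 101 of 104 higher and 223 of 244 lower genes had the same sign in R122C. Of the R122C calls, 45 of 50 lower genes had the same sign in WT and 1 of 5 higher genes, Top2a. Across the 17155 genes the log2 differences of the genotypes had a Pearson correlation of 0.575 and a Spearman correlation of 0.488, over genes that are not independent replicates.

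**Figure D2:**
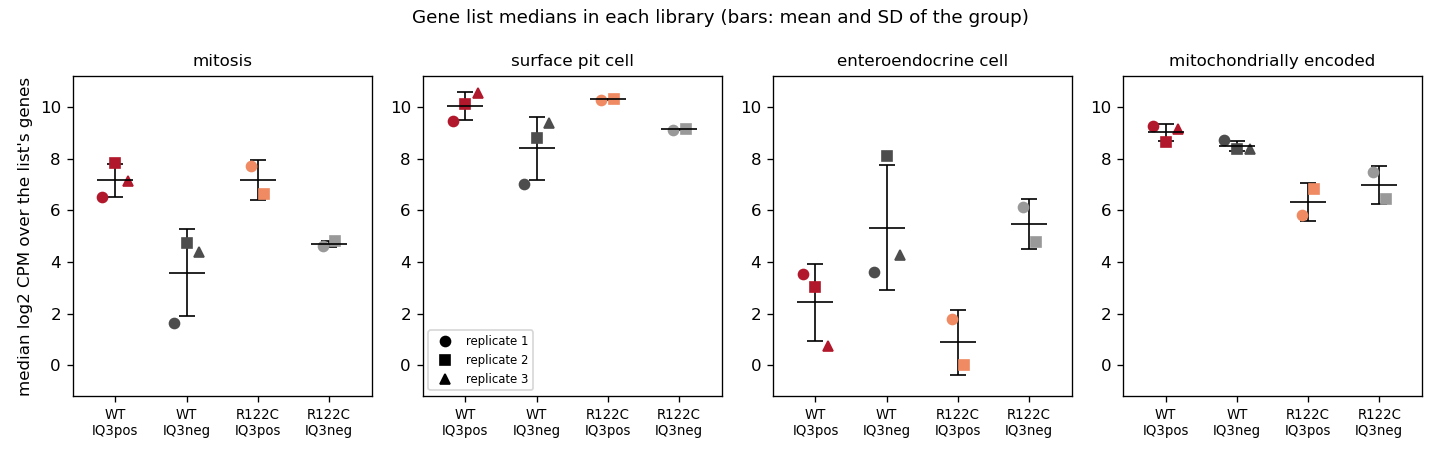
Median log2 CPM over the genes of a list (y axis) in each of the 10 libraries, for mitosis, surface pit cell, enteroendocrine cell and mitochondrially encoded genes, with symbols for the replicate number and bars for the mean and SD of a group (n = 3 in WT and n = 2 in R122C). The mitosis medians are 6.51 to 7.81 in WT IQ3pos and 1.64 to 4.73 in WT IQ3neg, and the mitochondrially encoded medians are 8.35 to 9.27 in WT and 5.81 to 7.50 in R122C.

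Between genotypes within IQ3pos, transcripts encoded by mitochondrial DNA were lower in R122C as a set. They took 1.26% (95% interval 1.261 to 1.265) and 1.80% (1.800 to 1.803) of the reads in the R122C IQ3pos libraries, against 10.9%, 7.40% and 5.84% in WT IQ3pos. All 13 differences were below 0, with a median of -2.69 (camera adjusted p = 3.2e-24, and adjusted p = 0.327 with an estimated correlation). None passed over all genes, and 12 were lower when adjusted over the list alone. mt-Co1, a subunit of cytochrome oxidase, stood at 10.31 ± 0.413 against 13.13 ± 0.412 (log2 difference -2.82 ± 0.595, adjusted p = 0.267), and with quantile normalization at -3.82 (adjusted p = 0.0393, in a range of 0.0393 to 1 over its alternatives). mt-Cytb, a subunit of the cytochrome bc complex, differed by -2.23 ± 0.713 (adjusted p = 0.624). In the same libraries the nuclear RNAs Malat1 and Neat1, chosen after their values were seen, differed by -3.22 ± 0.628 and -3.15 ± 0.555 without passing (adjusted p = 0.226 and 0.151), while Neat1 was called with median centring and by voom. In the only title code found in both genotypes, with 1 library of each per fraction, the list's median difference was -2.73.

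Cell division and lineage genes did not pass between genotypes in IQ3pos. R122C minus WT was 0.18 ± 0.519 for Top2a, 0.33 ± 0.523 for Mki67 and 0.96 ± 0.694 for Stmn1 (adjusted p = 1, 1 and 0.963), and in the shared title code it was 0.14, 0.51 and 0.67. It was -0.12 ± 0.558 for Gkn1, -0.08 ± 0.746 for Muc5ac, 0.23 ± 0.615 for Pgc, -0.28 ± 0.526 for Cblif and 0.11 ± 0.433 for Chga, each with adjusted p = 1. The sign for Muc5ac turned with median centring. In 1 or more alternatives the sign also turned for Top2a, Mki67, Gkn1, Cblif and Chga, but not for Stmn1 or Pgc. Lrig1 differed by -1.06 ± 0.914 (0.965), Cdkn1a by -1.66 ± 0.536 (0.631) and Sst by -1.14 ± 0.415 (0.779). The mitosis list had a median of 0.27 (camera adjusted p = 0.316), DNA replication 0.23 (0.146), pit cells 0.19 (0.573), mucous neck cells 0.48 (0.144), chief cells -0.14 (0.573), parietal cells -0.26 (0.14), enteroendocrine cells -0.25 (0.144), stem and progenitor candidates 0.11 (0.573) and the nuclear respiratory chain -0.04 (0.331). In the shared title code these medians were 0.14, 0.30, 0.22, 0.49, 0, -0.25, 0, 0.21 and -0.14.

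Immune cell genes were the other set called lower in R122C IQ3pos (17 genes, median -0.66, camera adjusted p = 0.0212, and adjusted p = 0.833 with an estimated correlation), with a median of 0 in the shared title code. Lyz2, the lysozyme gene of myeloid cells, stood at 1.95 and a listed 0 in R122C against 7.69, 5.40 and 2.84 in WT (adjusted p = 0.629). The set's adjusted p was 0.167 without WT IQ3pos replicate 1, 0.16 without R122C IQ3pos replicate 2 and 0.0585 with quantile normalization, and the median was -1.36 without WT IQ3pos replicate 2, -1.01 without R122C IQ3pos replicate 1 and -0.30 (adjusted p = 0.532) with the title code as a term. Limma called 0 genes here, with 930 at an unadjusted p under 0.05 where chance gives 857.8, a smallest adjusted p of 0.0712, and 65 called by voom on the recovered reads. Without R122C IQ3pos replicate 1 it called 8 genes, and without WT IQ3pos replicate 1 it called 2, Gc and Ccn3, named after their values were seen.

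Between genotypes within IQ3neg, 17 sets were called with the preset correlation and none with an estimated correlation, and no single gene passed. Mitosis genes were higher in R122C (24 of 25 differences above 0, median 1.23, camera adjusted p = 8.32e-08, and adjusted p = 0.626 with an estimated correlation). The proliferation genes differed by 0.44 ± 0.523 for Mki67, 0.28 ± 0.519 for Top2a, 1.59 ± 0.768 for Ccnb2, a mitotic cyclin, and 1.54 ± 0.694 for Stmn1, each with adjusted p = 1. In the shared title code the mitosis median was 0.45, with -0.22 for Mki67 and -0.26 for Top2a. The mitosis median was 0.46 without WT IQ3neg replicate 1, the library with 32.1% of its reads on Clps, and 1.87 without WT IQ3neg replicate 2. With 9 mitosis genes listed at 0 in WT IQ3neg replicate 1, the differences of those genes depend on the floor. DNA replication (0.77, camera adjusted p = 0.000184) and MYC targets (0.75, 0.000282) were higher too, each with adjusted p = 0.626 with an estimated correlation. Without WT IQ3neg replicate 1 their medians were 0.18 and 0.13, and in the shared title code they were 0.35 and 0.28.

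Sets of secretory and surface lineages were also higher in R122C IQ3neg: pit cells (median 0.74, camera adjusted p = 0.00353), mucous neck cells (1.08, 0.00267), metaplasia genes (0.62, 0.00452), stem and progenitor candidates (0.58, 0.022) and parietal cells (0.49, 0.0472), each with adjusted p = 0.626 with an estimated correlation. Examples were Tff1 (1.14 ± 0.582), Tff2 (1.06 ± 0.668) and Spink4, a secreted inhibitor of proteases (2.08 ± 0.81), each with adjusted p = 1. In the shared title code the medians were 0.30, 0.42, 0.09, 0.08 and 0.27. Mitochondrially encoded transcripts were lower (median -1.79, camera adjusted p = 1.99e-17, and adjusted p = 0.626 with an estimated correlation), with 10 of 13 lower when adjusted over the list alone, -0.69 in the shared title code and -1.03 without R122C IQ3neg replicate 2. mt-Co1 differed by -1.96 ± 0.595 (adjusted p = 0.778), and in the same libraries Malat1 and Neat1 differed by -2.64 ± 0.628 and -2.24 ± 0.555 (adjusted p = 0.376 and 0.425). Immune cell genes (-1.32, 1.82e-06), fibroblast and muscle genes (-0.92, 0.00654), interferon response (-0.86, 0.0177) and immediate early genes (-0.45, 0.013) were lower, with adjusted p = 0.626 with an estimated correlation and -0.95, -0.06, -1.19 and 0.16 in the shared title code. Cholesterol synthesis (0.59, 0.0131) and glycolysis (0.55, 0.0177) were higher with 0.626, as were ribosomal proteins (0.29, 0.00654) with 0.812 and the respiratory chain (0.23, 0.0378) with 0.843, and the shared title code gave -0.03, 0.26, -0.33 and -0.37. Chief (0.10, 0.974), enteroendocrine (-0.11, 0.144), tuft (0.38, 0.606) and antral (1.06, 0.148) cell sets had no call.

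Several of these IQ3neg calls rested on 1 library. Without WT IQ3neg replicate 1, adjusted p was 0.128 for pit cells, 0.201 for stem candidates, 0.413 for parietal cells, 0.108 for immediate early genes, 0.28 for cholesterol synthesis, 0.473 for glycolysis, 0.79 for the respiratory chain, 0.632 for ribosomal proteins, 0.201 for immune cells and 0.742 for fibroblasts, and the neck, metaplasia and interferon medians were 0.47, 0.25 and -1.32. In that fit the medians of parietal cells (-0.028), glycolysis (-0.016), the respiratory chain (-0.042) and ribosomal proteins (-0.0062) changed sign. Without R122C IQ3neg replicate 2 it was 0.203 for neck cells, 0.0811 for metaplasia, 0.148 for stem candidates, 0.0743 for parietal cells and 0.203 for cholesterol synthesis, and the immediate early (0.28, adjusted p = 0.536), respiratory (-0.12, 0.00538) and ribosomal (-0.16, 0.00457) medians changed sign. Without R122C IQ3neg replicate 1 it was 0.448 for interferon response (median -0.21), 0.0966 for stem candidates, 0.355 for parietal cells (median 0.24), 0.438 for glycolysis and 0.0816 for fibroblasts, the immediate early median was -1.36, and the pit, respiratory and ribosomal medians were 1.13, 0.56 and 0.74. Without WT IQ3neg replicate 3 it was 0.291 for interferon response, with medians of 1.29 for pit cells, 1.65 for neck cells, 0.83 for glycolysis, 0.38 for the respiratory chain, 0.52 for ribosomal proteins and -1.38 for fibroblasts. Without WT IQ3neg replicate 2 the parietal and immediate early medians were 0.78 and -0.29. With the title code as a term the respiratory and ribosomal medians were -0.11 and -0.16. Limma called 0 genes in this comparison, with 629 at an unadjusted p under 0.05 and 3 called by voom (Gm6304 and 2 immunoglobulin kappa variable segments, singled out after their values were seen), and it called 16 and 14 without R122C IQ3neg replicates 1 and 2.

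Whether the genotype effect differed between the fractions was tested as an interaction. No gene passed in limma, with 444 at an unadjusted p under 0.05, a smallest adjusted p of 1 and 0 called by voom. For Mki67 the interaction was -0.11 ± 0.739, for Top2a -0.09 ± 0.734, for Gkn1 -0.91 ± 0.789, for Atp4b -1.18 ± 0.96 and for mt-Co1 -0.85 ± 0.841, each with adjusted p = 1. The sign turned with median centring and with quantile normalization for Mki67 and Top2a. The sets of mitosis (median -1.13, camera adjusted p = 0.0108), parietal cell (-0.79, 0.00357), respiratory chain (-0.29, 0.0147), mitochondrially encoded (-0.98, 0.00357) and ribosomal protein genes (-0.39, 0.00357) were lower, all with adjusted p = 0.979 with an estimated correlation. For the mitochondrially encoded set, the median of IQ3pos minus IQ3neg was -1.58 in R122C replicate 1 but 0.996 in R122C replicate 2. In WT replicates 1, 2 and 3 it was 0.56, 0.63 and 0.86. Mitosis had a median of -0.20 (adjusted p = 0.441) without WT IQ3neg replicate 1 and -0.59 (0.757) without R122C IQ3pos replicate 2, and its call was also lost without WT IQ3pos replicates 2 (0.627) and 3 (0.0566) and R122C IQ3neg replicate 2 (0.424). The parietal call was lost without WT IQ3pos replicate 1 (0.118), WT IQ3neg replicate 1 (0.0743), R122C IQ3neg replicate 1 (0.0785) and R122C IQ3pos replicate 2 (0.11), and the median was -1.26 and -1.29 without WT and R122C IQ3neg replicate 2. The mitochondrially encoded median was -0.62 (adjusted p = 0.118) without WT IQ3pos replicate 1, -0.58 (0.238) without WT IQ3neg replicate 2, -0.58 (0.502) without R122C IQ3pos replicate 1 and -0.23 (0.575) without R122C IQ3neg replicate 1, which ended the call in each fit, and it was -1.78 (4.59e-07) without R122C IQ3neg replicate 2. The respiratory and ribosomal calls were lost without WT IQ3pos replicate 1 (adjusted p = 0.54 and 0.0553), WT IQ3neg replicate 1 (medians -0.018 and -0.059, adjusted p = 0.463 and 0.2), R122C IQ3pos replicate 1 (-0.19 and -0.16, 0.557 and 0.819) and R122C IQ3neg replicate 2 (0.03 and 0.07, 0.459 for both). Their medians were -0.65 and -0.84 without R122C IQ3neg replicate 1, -0.52 and -0.61 without WT IQ3neg replicate 3, and -0.47 and -0.68 without R122C IQ3pos replicate 2, and the respiratory median was -0.45 without WT IQ3neg replicate 2. Pit cells (-0.56, 0.38), chief cells (-0.43, 0.733), stem candidates (-0.63, 0.541) and enteroendocrine cells (-0.27, 0.923) had no call. Median centring shifted the median of all genes by 0.145 in this contrast and quantile normalization by 0.109, and both left the respiratory chain without a call (medians -0.15 and -0.16, adjusted p = 0.0908 and 0.144) and put the ribosomal median at -0.25 and -0.24. In simulated data a log2 interaction of 4 was recovered for 19.7% of changed genes, against 80.3% for the same size between the WT fractions. The changed genes all had a mean log2 CPM of at least 4.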

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

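The interaction tests by camera and fry were set before the data were examined, while the fits without a library and each test of an explanation in this part were chosen after the result was seen. The genotype effect differed between the fractions, by camera on the interaction with the preset correlation, for 5 lists: mitosis (median -1.13, adjusted p = 0.0108), parietal cell (-0.79, 0.00357), respiratory chain (-0.29, 0.0147), mitochondrially encoded (-0.98, 0.00357) and cytosolic ribosomal proteins (-0.39, 0.00357). All had adjusted p = 0.979 with an estimated correlation and 0.99 by fry, and no single gene passed. The 2 R122C pairs had opposite signs for the mitochondrially encoded list. Its median of IQ3pos minus IQ3neg was -1.58 in replicate 1 and 0.996 in replicate 2, against 0.56, 0.63 and 0.86 in the WT pairs. The mitosis median was -0.20 (0.441) without WT IQ3neg replicate 1, -0.59 (0.757) without R122C IQ3pos replicate 2 and -0.58 (0.000873) without both libraries of WT replicate 1. The mitochondrially encoded median was -0.23 (0.575) without R122C IQ3neg replicate 1 and -1.78 (4.59e-07) without R122C IQ3neg replicate 2. The parietal median was -0.20 (0.289) without both libraries of WT replicate 1. The respiratory and ribosomal medians were 0.03 and 0.07 without R122C IQ3neg replicate 2, and 0.05 and -0.09 without both libraries of WT replicate 1, with adjusted p = 0.459, 0.459, 0.993 and 0.289.

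In WT IQ3neg replicate 1, 9 mitosis genes were listed at 0, so the differences of those genes depend on the 1 CPM floor. Mitosis genes were higher in R122C IQ3neg than in WT IQ3neg, by a median of 1.23, while in IQ3pos the median was 0.27. WT IQ3neg replicate 1 carries part of this: the median was 0.459 without both libraries of WT replicate 1 and remained past the threshold with the preset correlation (adjusted p = 1.58e-05, and adjusted p = 0.577 with an estimated correlation, against 0.626 with all libraries), which neither excludes that library as the source nor leaves the size as it was. A candidate explanation is IQ3pos cells in the R122C IQ3neg sort, and the pit cell list, high in IQ3pos, was also higher, by 0.737, but a change in the IQ3neg cells themselves allows the same. Within the title code that both genotypes share the median was 0.45 with 1 library per genotype. With the code as a term it was 0.798 (camera adjusted p = 2.98e-05, and adjusted p = 0.9 with an estimated correlation). That fit's genotype difference, averaged over the fractions, rests on the same shared code and is no separate evidence. The code and the genotype therefore cannot be told apart for this list. A biological effect of R122C stays open as well, untested beyond these values.

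Mitochondrially encoded transcripts were lower in R122C, by a median of -2.69 in IQ3pos and -1.79 in IQ3neg. WT replicate 1 does not account for it: without both of its libraries the medians were -2.56 and -1.53, both past the threshold with the preset correlation, with adjusted p = 0.911 and 0.571 with an estimated correlation, against 0.327 and 0.626 with all libraries. Fewer mitochondria with the transcripts of both genomes lowered alike is argued against, since the nuclear respiratory chain list had medians of -0.0422 in IQ3pos (SD over its genes 0.46) and 0.234 in IQ3neg (SD 0.345). These values do not bear on fewer mitochondria with nuclear transcripts unchanged, which stays open. A difference between the title codes stays open. Within the title code that both genotypes share the medians were -2.73 in IQ3pos and -0.692 in IQ3neg. With the code as a term they were -2.23 and -1.24 (camera adjusted p = 2.73e-13 and 7.64e-06, and adjusted p = 0.973 and 0.9 with an estimated correlation). That fit's genotype difference, averaged over the fractions, rests on the same shared code and is no separate evidence. In IQ3pos the difference was as large within the code as over all libraries, but on 1 library per genotype and a code of unknown meaning. Malat1 and Neat1, nuclear RNAs chosen after their values were seen, differed by -3.22 and -3.15 in IQ3pos and -2.64 and -2.24 in IQ3neg without passing, so a difference in RNA composition or quality between the libraries stays open, as does an effect of R122C, both untested.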

How the results depend on the processing

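The fits without both libraries of WT replicate 1, and the list tests under median centring, the block, the title code and each library left out, were chosen after the data were seen. Of 2730 comparisons of a single gene's result with an alternative, 2368 kept their sign and side of the threshold, 227 no longer passed, 33 newly passed, and 102, over 31 results and called in neither fit, changed sign. No called value changed sign. Genes called between the WT fractions (348) were 191 with no filter, 549 at 5 CPM, 594 with quantile normalization, 898 with centring, 702 with library weights and 674 with the random effect. They were 34 with only these groups, all lower in IQ3pos, and 1752 by voom, of which 347 were among the 348. They were 78 to 403 with 1 library left out and 220 without both libraries of WT replicate 1. Between the R122C fractions (55) they were 87 with centring, 146 without trend, 127 with weights, 0 with only these groups, 90 with the random effect, 210 by voom, 42 without both libraries of WT replicate 1 and 17 to 41 with 1 library left out. The fits on only the groups compared have fewer samples to estimate the spread. R122C against WT in IQ3pos (0) gave 1 at 5 CPM (Gm12940), 6 with quantile normalization, 2 with centring (Neat1 and Gm12940), 7 without trend, 1 with robust moderation (Gm12940), 6 with weights, 65 by voom, 2 without both libraries of WT replicate 1 (Gc and Ccn3) and 0 to 8 with 1 library left out. In IQ3neg (0) it gave 4 with no filter (Adgrf5, Pcdhb19, Il12b and Rdh16f1), 9 with weights, 3 by voom and 0 to 16 with 1 left out. The interaction gave 0 genes in every alternative. The cause of the changes in count between fits was not tested.

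Libraries of a genotype that share a number also share a title code and a number of pooled mice, but the labels do not say that they come from the same mice. Deviations from the group means correlated at 0.162, 0.115, 0.0808, 0.105 and 0.105 in the 5 pairs, not all above 0.1, although 5 of 5 IQ3pos libraries correlated best with the IQ3neg library of their own number, a hint from the data and not the design. With 2 libraries in each R122C group the deviations mirror each other, so the 2 R122C correlations are 1 value and their matches are not independent. Both libraries of each WT number and of R122C replicate 1 had the same pattern of Xist and Ddx3y. In R122C replicate 2 Ddx3y was above 0 in both libraries and Xist in 1. With the number within each genotype as a replicate block, 364 genes were called between the WT fractions (189 higher and 175 lower), 256 of them among the 348. Between the R122C fractions 31 were called (2 higher and 29 lower). Of the genes named by the rule, Aspm, Trpm5 and Prss1 in WT (adjusted p = 0.0518, 0.0667 and 0.059) and Depdc7, Ccdc63, Rhobtb2, Pcsk1, Cblif and Ceacam10 in R122C (0.0507 to 0.122) no longer passed with that block. Stmn1, Muc5ac and Tff2 newly passed in WT (0.0314, 0.0269 and 0.0371). The genotype comparisons used another block, the number across genotypes, which joins WT and R122C libraries of different title codes. It called 1 gene in IQ3pos, Apoe. Apoe and the genes of the paragraph above were chosen after their values were seen.

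Of the 48 list calls, 4 held with an estimated correlation and 4 with fry (2, 2, 0, 0 and 0 lists in the 5 comparisons for each), 44 with quantile normalization and 46 with centring. Lists called between genotypes in IQ3neg (17) were 9 with the title code as a term, 7 without both libraries of WT replicate 1 and 7 to 19 with 1 library left out, in IQ3pos (2) 2 to 5, and in the interaction (5) 3 without both libraries of WT replicate 1 and 1 to 8. Directions changed in IQ3neg for immediate early genes (-1.36 to 0.28 with 1 library left out), parietal cells (-0.028 to 0.78), glycolysis (-0.016 to 0.83), respiratory chain (-0.12 to 0.56, and -0.11 with the title code) and ribosomal proteins (-0.16 to 0.74, and -0.16), and in the interaction for respiratory chain (-0.65 to 0.027, and 0.054 without both libraries of WT replicate 1) and ribosomal proteins (-0.84 to 0.071), and the cause was not tested. Where leaving out a library left 1 library in an R122C group, that library was assumed to vary like the other groups. At 1 CPM a library held 47.4 to 264.8 reads, so the listing sets the lowest level that can be seen.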

Other observations

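The few-molecules test and the splits below were set before their results were seen, and the depth test was chosen after. Genes named in this part, other than Jchain, Xist and Ddx3y, were chosen after their values were seen. No list of such genes was fixed or tested, so the values stand for the single genes alone. Among genes called higher in WT IQ3pos, Gsr, glutathione reductase (chromosome 8, 33652523 to 33698163), rose by 2.80 ± 0.458 (SE, adjusted p = 0.0119 in limma), the glutathione transferase Gsta3 by 2.46 ± 0.444 (0.0178), Gclc, the catalytic subunit that starts glutathione synthesis, by 2.45 ± 0.526 (0.0373), the aldehyde dehydrogenase Aldh3a1 by 2.30 ± 0.385 (0.0132), the malic enzyme Me1 by 2.31 ± 0.52 (0.0433) and Ugdh, a UDP-glucose dehydrogenase, by 2.24 ± 0.449 (0.0288). Each was higher in IQ3pos in 3 of 3 WT title codes. In R122C the differences were 2.19, 1.57, 1.54, 1.11, 2.02 and 1.36, with adjusted p between 0.186 and 0.551, so none passed there, and the interaction had adjusted p = 1 for every gene tested. The WT calls depended on single libraries: over these 6 genes adjusted p was 0.0327 to 0.104, 0.0407 to 0.134 and 0.0687 to 0.166 without IQ3pos replicates 1, 2 and 3, and 0.0273 to 0.0758, 0.0553 to 0.121 and 0.0193 to 0.0407 without IQ3neg replicates 1, 2 and 3. Hes1, a transcription factor of the Notch pathway, rose by 2.26 ± 0.492 in WT (0.0389) and was 2.15 higher in R122C (0.235), and its WT call held without IQ3neg replicate 1 but not without any other single WT library (0.0728 to 0.129). Sprr2a1 rose by 3.42 ± 0.483 (0.00464) and held without any single WT library, but it overlaps the near-identical Sprr2a2 on chromosome 3, so the gene of origin is uncertain.

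Igha, the constant region of immunoglobulin A and a transcript of plasma cells, which an EpCAM sort should remove, stood at 3.50 and a listed 0 in 2 libraries in WT IQ3pos against 7.79, 7.10 and 5.37 in IQ3neg (adjusted p = 0.0141), and was listed at 0 in both R122C IQ3pos libraries against 8.89 and 8.24 (0.00974). Its WT call held without IQ3pos replicate 1 and without IQ3neg replicate 3, with adjusted p of 0.056 to 0.0774 without each of the others, and its R122C call was lost without any 1 of the 4 libraries (0.0714 to 0.172). Jchain stood at 7.61, 6.01 and 5.83 in WT IQ3neg and 8.14 and 8.27 in R122C IQ3neg. Ttr, transthyretin, fell by 2.34 (0.00338) and Rbp4, the retinol carrier, stood at 3.61, 2.62 and a listed 0 in IQ3pos against 7.03, 7.58 and 7.15 in IQ3neg (0.00735, and 0.0596 without IQ3neg replicate 2), while Ahsg, fetuin A, was listed at 0 in every IQ3pos library of WT against 5.83 ± 0.334 in IQ3neg (0.00259). The WT calls of Ttr and Ahsg held without any single WT library.

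Between genotypes, several single genes had lower values in R122C in both fractions without passing, and 5 of them are given here. In IQ3pos the difference was -3.22 ± 0.628 for Malat1 (adjusted p = 0.226), -3.15 ± 0.555 for Neat1 (0.151), -1.94 ± 0.356 for Sfpq (0.167), -2.23 ± 0.402 for Srsf2 (0.153) and -2.84 ± 0.44 for Paxbp1 (0.0772), of which Neat1 was called with median centring, Srsf2 with quantile normalization, Paxbp1 with library weights, and Neat1, Sfpq, Srsf2 and Paxbp1 by voom. In IQ3neg it was -2.64, -2.24, -1.79, -1.78 and -1.96 (0.247 to 0.425), and in the title code that both genotypes share it was -2.11, -2.83, -1.86, -2.26 and -2.80 in IQ3pos and -1.30, -1.87, -2.07, -1.77 and -1.82 in IQ3neg. The sex-linked genes differed between pools: Ddx3y, on the Y chromosome, was listed at 0 and Xist, expressed from an inactive X chromosome, stood at 7.07 and 7.30 in the WT replicate 2 libraries, Ddx3y stood at 6.74 and 6.67 with Xist at 0 in WT replicate 1, and both were above 0 in WT replicate 3 (4.54 and 5.08 for Ddx3y, 7.80 and 6.62 for Xist). In R122C replicate 1 Xist stood at 4.03 and 6.24 with Ddx3y at 0, and in R122C replicate 2 Ddx3y stood at 4.38 and 6.15 with Xist at 1.58 and a listed 0.

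Of 39848 cases of a gene at 8 CPM or more in its highest library of a group, 5646 (14.2%) stood at an eighth of that or less in another library of the group, 4250 of them at a listed 0. Sequencing depth is argued against in R122C, since the deeper library of each fraction held more of these genes than the shallower one, 538 against 354 in IQ3pos (a ratio of 1.52) and 441 against 69 in IQ3neg. In WT replicate 1, the shallowest, held more than the deepest library, 1565 against 986 in IQ3pos and 1254 against 194 in IQ3neg (a ratio of 0.155 of deepest to shallowest), so a property of replicate 1 that goes with its depth stays open, although 8 CPM stood for at least 379 reads and Poisson counting alone gives 1.06e-102 cases over the 4 groups. Few starting molecules amplified by PCR may account for them, as a hypothesis: the share was 33.1% at 8 to 16 CPM and 1.76% at 64 CPM or more, a ratio of 18.8, which any noise that grows at low levels allows as well. No biological explanation was tested, and differences between the mice of the pools stay open.

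The 6 WT libraries can be split into 3 and 3 in 10 ways. The real split called 348 genes and the highest of the others 0, with 1 split calling as many, and 10 splits are too few for a share under 0.05. Every other split also mixes the fractions in both groups. The fraction difference then enters the spread, so few calls would follow there in any case.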
